A study of Mus musculus with 7 samples.

How the data were processed

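Bone marrow dendritic cells from C57Bl/6J mice given vehicle (4 libraries) or R848 (3 libraries) were profiled by RNA sequencing. Per the labels' protocols, RNA was purified with a column kit for small samples and libraries were made with the KAPA RNA HyperPrep kit. The authors deposited 1 table of estimated counts per gene and library, not scaled between libraries. Per the submitters' processing notes, Partek, Trim Galore, STAR 2.5.3a and the mouse build mm10 were used, with no role or order given. The gene annotation, the strand setting and any filter on reads are not given in the sources used here. Between 33.3% and 42.0% of the deposited expected count values of a library differed from a whole number by more than 0.01, so reads were shared between features, and genes with close paralogs or an antisense partner have uncertain levels.

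The table held 23750 rows, each with a symbol, chromosome, start, stop and strand. The stop column lay 1 base past the last base, so ends are given as that column minus 1. After this step 97.1% of rows had the symbol, coordinates and strand of GENCODE M21, and 99.3% had a symbol of that annotation. Columns were assigned to samples by the names in the labels, and groups by the labels' agent. No column of values was left unused (0).

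Counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 18292 genes and at least 99.9% of the counts of each library. Library sizes were scaled with TMM. The main test was edgeR's quasi-likelihood F-test (robust, group as the only term), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The SE of a log2 fold change was its absolute value divided by the square root of F. The common biological coefficient of variation was 0.367. CPM values are counts divided by the TMM-scaled library size, and log2 CPM values for the principal components had 0.5 added. A floor of 3 counts corresponded to 0.0811 to 0.166 CPM in single libraries. Total counts were 18213122 to 37077706, and intervals and floors cover counting error only.

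The 33 gene lists (responses, cell type markers and sort gate genes) were fixed from textbook knowledge. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Of these, 14 passed, 9 upward and 5 downward. With a correlation estimated per list, 0 of the camera calls held (lowest adjusted p = 0.0604; 4 lists had an unadjusted p under 0.05). Fry, which tests whether a list's genes move one way on balance, called 10 lists. Among these 10 were the conventional type 2 dendritic cell markers, which camera did not call. Fry did not call the erythroid, megakaryocyte, immediate early, ribosomal and mitochondrially encoded lists, which camera called. In 6 lists the median and the camera direction differed in sign, and none of them was called. The lists hold 737 distinct tested genes, and some genes belong to more than 1 list.

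Genes were named by a rule. It took the 6 largest rises and the 6 largest falls among genes past the threshold with a mean log2 CPM of at least 2, non-overlapping groups and a symbol that is not a predicted or clone name. It added up to 2 members with the lowest p per response list, the member with the lowest p and the most abundant member per cell type list, all gate genes, Tlr7, Tlr8 and Irf7. Because the rule picked sex-linked genes, the same ranking off the X and Y chromosomes was added after the data were examined. The rule and this addition gave 86 genes, of which 84 could be tested. The values of 1 gene picked by the rule are not reported. Any other gene named was chosen after its values were seen, and is said to be so or stands among the values of its list.

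The design, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were RLE, total-count and upper-quartile scaling, DESeq2's Wald test, limma-voom with quality weights, no filter beyond 1 count, and a filter of at least 5 CPM in at least 3 libraries. Others were the replicate number as a block, leaving out each library, an adjusted p under 0.01, a fold of at least 2, glmTreat against 1.5-fold, and the 2 other list tests. Chosen after seeing the data were a test of autosomal genes alone and offsets for GC content and transcript length. Fitted to log2 CPM minus the gene's mean over the libraries, the offsets remove each library's loess trend (span 0.5) with GC content and length. These properties came from the longest GENCODE M21 transcript of each symbol, which 99.5% of tested genes had.

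The scripts were tested on simulated counts drawn from the real means, dispersions and library sizes for R848 against vehicle, with 200 genes changed. Of the genes tested in that run (17649), edgeR recovered 2 of 67 changed 1.5-fold, 10 of 67 changed 2-fold and 45 of 66 changed 4-fold, with 4 false calls. The median fitted folds were 1.59, 1.96 and 4.05. With no change simulated it made 0 calls. A list of 19 genes doubled in level, a 2-fold shift, was called with camera (adjusted p = 6.60e-15) and 0 other lists were. Genes were drawn independently there, while the estimated correlation within a real list was up to 0.831 (mitochondrially encoded genes). The simulation therefore does not test false list calls among genes that vary together. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.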

Results

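RNA sequencing measured gene expression in dendritic cells sorted from the bone marrow of mice. R848 is a small-molecule agonist of the endosomal receptors TLR7 and TLR8, which sense single-stranded RNA. Animals received a single dose of 100 ug R848 or vehicle alone. The cells were collected 24 h after R848, and at a time that the labels do not give after vehicle, as cells with high MHC class II, high CD11c and high GFP from the CX3CR1 locus, without Gr-1 or B220. The table held 4 vehicle and 3 R848 libraries and 23750 genes. Total counts ran from 24196608 to 37077706 in the vehicle libraries and from 18213122 to 24665345 in the R848 libraries. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 17.0 or more), so each library was counted as 1 sample. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical in part. Levels below are TMM-scaled CPM, as mean ± SD with n = 4 for vehicle and n = 3 for R848, and fold changes are those of edgeR on the log2 scale with their standard error (SE).

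The libraries of each group lay apart from the other group on the first principal component, which held 50.7% of the variance of log2 CPM. Vehicle replicates 1 and 3 were separated on the second component, which held 18.6%. Within a group, log2 CPM correlated across genes at r of 0.980 to 0.985 between R848 libraries and of 0.950 to 0.976 between vehicle libraries. Genes are not independent replicates, so these coefficients only describe the libraries.

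**Figure D1:**
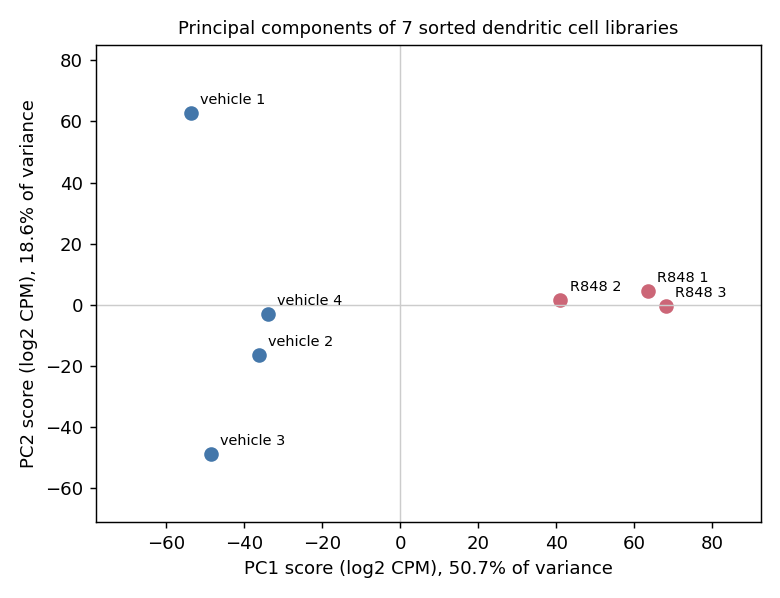
Scores of the 7 libraries on the first and second principal component of log2 CPM, with vehicle in blue and R848 in red and each point a library. The 3 R848 libraries lie at PC1 scores of 41.0 to 68.0 and the 4 vehicle libraries at -53.8 to -34.0.

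Sex-linked genes separated the groups completely. Xist, the non-coding RNA of the inactive X chromosome in females, stood at 0.363 ± 0.727 CPM in vehicle and 1588 ± 198 CPM in R848 libraries. Ddx3y and Uty on the Y chromosome were at 55 ± 13 and 21.1 ± 5.83 CPM in vehicle and had no count in any R848 library, which makes them at least 1159-fold and 435-fold lower over the group at a floor of 3 counts. Eif2s3y had a single count over the 3 R848 libraries and 6215 over the vehicle libraries, a ratio of vehicle to R848 of 3234 (95% exact counting interval 580.2 to 127756, counting error only). Kdm5d fell from 55.8 ± 11.3 to 0.273 ± 0.269 CPM. All 4 vehicle libraries were therefore of male type and all 3 R848 libraries of female type, and the labels used here give no sex. The names of the table's columns also carry run numbers that begin alike within a group and differently between the groups. Sex type and column series were thus the same split as treatment, no library broke that split, and neither can be separated from R848 in any comparison below.

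The genes of the sort markers came first, because they describe the identity of the sorted cells. Cx3cr1, the locus of the GFP reporter and a fractalkine receptor gene, fell from 254 ± 44.1 to 107 ± 19.8 CPM (log2 fold change -1.25, SE 0.18, adjusted p = 9.36e-04). The labels call the mice wild type and do not give the number of reporter alleles in either group, so this fall cannot be read as an effect on the intact gene alone. Itgax, which encodes CD11c, rose from 417 ± 106 to 757 ± 78 CPM (log2 fold change 0.86, SE 0.19, adjusted p = 0.0142). Ly6c2, which encodes a Gr-1 antigen, rose from 77.2 ± 21.1 to 145 ± 16.8 CPM (log2 fold change 0.91, SE 0.21, adjusted p = 0.0152). The MHC class II genes H2-Aa and H2-Ab1 were at 5421 ± 203 and 4398 ± 1029 CPM in vehicle against 4288 ± 546 and 3329 ± 488 CPM in R848 and did not pass the test (adjusted p = 0.166 and 0.264). H2-Ab1 passed as lower with GC and length offsets alone (range over alternatives 0.0420 to 0.683). Ptprc, which encodes CD45 and its B220 form, stood at 1295 ± 199 and 1777 ± 173 CPM (adjusted p = 0.0857), and passed without vehicle replicate 1 (adjusted p = 0.0427; range over alternatives 0.0104 to 0.334). It also passed with DESeq2, limma-voom and the GC and length offsets. Ly6g and Ly6c1 were too low to test, with means of 0.142 ± 0.167 and 0.0203 ± 0.0405 CPM in vehicle and 0.427 ± 0.434 and 0.361 ± 0.349 CPM in R848. In all, 2 of the 6 tested gate genes were higher and 1 lower (3 and 2 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.982). The calls on Itgax and Ly6c2 were lost without R848 replicate 1, that on Itgax also without R848 replicate 3 and that on Ly6c2 without R848 replicate 2 (adjusted p 4.86e-04 to 0.0701 and 6.59e-04 to 0.0682 over their alternatives).

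The comparison of R848 with vehicle asked how a single dose of the agonist changed the transcriptome of these marrow dendritic cells. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1212 of 18292 tested genes were higher and 852 lower in R848 at an adjusted p under 0.05, of which 829 and 440 changed at least 2-fold. With upper-quartile scaling, 1070 were higher and 1049 lower, so the excess of rises depended on the scaling. Of the calls on autosomes, 1195 were higher and 814 lower. The largest rises after Xist were in Grpr, a bombesin-family peptide receptor gene on the X chromosome (0.0270 ± 0.0540 to 11.2 ± 1.35 CPM), the phospholipase gene Pla2g4f (0.732 ± 0.816 to 94.7 ± 28.8 CPM), the immunoglobulin constant gene Ighg2b, the receptor-modifying gene Ramp3 (0.210 ± 0.121 to 21 ± 14.7 CPM) and the zinc-finger gene Zfp872 (0.161 ± 0.207 to 16.5 ± 5.11 CPM). Ighg2b stood at 6.03, 1.86 and 74.0 CPM in R848 replicates 1 to 3, and its call was lost without vehicle replicate 1 or 3 or R848 replicate 1, without the low-count filter and with the replicate block (adjusted p 3.64e-04 to 0.590 over its alternatives). Its log2 fold change was 6.67, and 3.87 without R848 replicate 3. After the 4 Y-linked genes, the largest falls were in the lectin gene Cd209d (18.4 ± 3.65 to 0.220 ± 0.108 CPM, log2 fold change -6.36, SE 0.39, adjusted p = 2.72e-06). Next came the macrophage elastase gene Mmp12 (8.95 ± 6.87 to 0.143 ± 0.143 CPM, log2 fold change -5.83, SE 0.97, adjusted p = 0.00278). The ranking was also made off the X and Y chromosomes, a choice made after the values were seen. It added the rises of Kdr (3.06 ± 1.41 to 292 ± 136 CPM, log2 fold change 6.55, SE 0.42, adjusted p = 1.37e-05), a VEGF receptor gene, and of the calcium channel gene Cacna1s (0.409 ± 0.373 to 25.5 ± 14.5 CPM). On the falling side it added the lysozyme gene Lyz1 (42.8 ± 23 to 0.886 ± 0.578 CPM), the lectin genes Mgl2 (201 ± 127 to 4.68 ± 1.47 CPM) and Cd209b (12.5 ± 6.42 to 0.379 ± 0.293 CPM), and Ccdc170 (12.7 ± 5.94 to 0.341 ± 0.0987 CPM). Limma-voom gave no call for Ighg2b, Ramp3, Mmp12 or Cacna1s. The total of 2064 calls fell to 1060 without R848 replicate 1 and to 1100 without R848 replicate 3, which leave 2 libraries in that group.

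Genes induced by interferon were higher in R848 libraries almost throughout. Of 40 interferon-stimulated genes tested, 35 rose and none fell (37 and 0 adjusted over the list alone), with a median log2 fold change of 1.63 (camera adjusted p = 3.39e-55; adjusted p = 0.0604 with an estimated correlation). Irf7, a transcription factor that drives type I interferon genes, rose from 75.6 ± 21 to 535 ± 55.2 CPM (log2 fold change 2.82, SE 0.22, adjusted p = 1.40e-05). Ifit2, which encodes an RNA-binding antiviral protein, rose from 30.2 ± 1.99 to 139 ± 15 CPM (log2 fold change 2.20, SE 0.14, adjusted p = 3.27e-06). Among 25 tested GTPase and other interferon-gamma-induced genes, 18 rose and none fell (21 and 0 adjusted over the list alone). The list's median log2 fold change was 1.66 (camera adjusted p = 5.86e-22; adjusted p = 0.0686 with an estimated correlation). Gbp5, a guanylate-binding protein gene, rose from 11 ± 1.74 to 156 ± 49.5 CPM (log2 fold change 3.83, SE 0.24, adjusted p = 2.72e-06). Its relative Gbp2 rose from 23.2 ± 4.77 to 179.7 ± 53.6 CPM (log2 fold change 2.95, SE 0.23, adjusted p = 1.51e-05). Paralogs in these families share sequence, and how shared reads were split is not given in the sources used here, so levels of single paralogs are uncertain.

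Genes of dendritic cell maturation moved furthest. Of 25 tested, 22 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 3.26 (camera adjusted p = 2.04e-64; adjusted p = 0.0604 with an estimated correlation). Ccr7, on chromosome 11 from 99144196 to 99155077 in mm10, encodes the chemokine receptor that guides dendritic cells to lymph nodes. It rose from 14.1 ± 6.01 to 699 ± 221 CPM (log2 fold change 5.64, SE 0.42, adjusted p = 3.45e-05). Cacnb3, a calcium channel subunit gene, rose from 13.4 ± 2.22 to 569 ± 204 CPM (log2 fold change 5.41, SE 0.26, adjusted p = 1.08e-06). Socs2, a suppressor of cytokine signalling, rose from 7.13 ± 2.19 to 217 ± 74.6 CPM (log2 fold change 4.94, SE 0.29, adjusted p = 2.16e-06). Among 24 targets and feedback genes of NF-kappaB, 11 rose and 3 fell (14 and 6 adjusted over the list alone). The list gave 1 fall without R848 replicate 1 or 3. The list's members had a median of 0.60 on the log2 scale (camera adjusted p = 5.38e-06; adjusted p = 0.376 with an estimated correlation). Relb, an NF-kappaB subunit gene that the maturation list also holds, rose from 50.7 ± 10.4 to 485 ± 128 CPM (log2 fold change 3.26, SE 0.22, adjusted p = 4.81e-06). The adaptor gene Traf1 rose from 70.8 ± 8.35 to 760.4 ± 238 CPM (log2 fold change 3.42, SE 0.21, adjusted p = 2.72e-06).

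MHC class I presentation genes rose in 19 of 21 cases and none fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.29 (camera adjusted p = 8.50e-40; adjusted p = 0.0604 with an estimated correlation). The non-classical class I gene H2-Q6 rose from 35.4 ± 6.11 to 675 ± 217 CPM (log2 fold change 4.25, SE 0.24, adjusted p = 1.50e-06). H2-Q7, its neighbour, rose from 69.7 ± 17.6 to 1008 ± 284 CPM (log2 fold change 3.85, SE 0.25, adjusted p = 3.49e-06). These neighbouring paralogs are close in sequence, so their separate levels are uncertain. MHC class II presentation genes moved both ways, with 4 of 15 higher and 3 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.560). The test found no fall without R848 replicate 3 and 1 fall without R848 replicate 1. H2-Eb2 rose from 8.25 ± 4.02 to 82.3 ± 11.3 CPM (log2 fold change 3.32, SE 0.30, adjusted p = 3.45e-05). H2-DMb2, which encodes a peptide-exchange subunit, rose from 61.3 ± 5.04 to 151 ± 25.7 CPM (log2 fold change 1.30, SE 0.15, adjusted p = 2.12e-04).

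**Figure D2:**
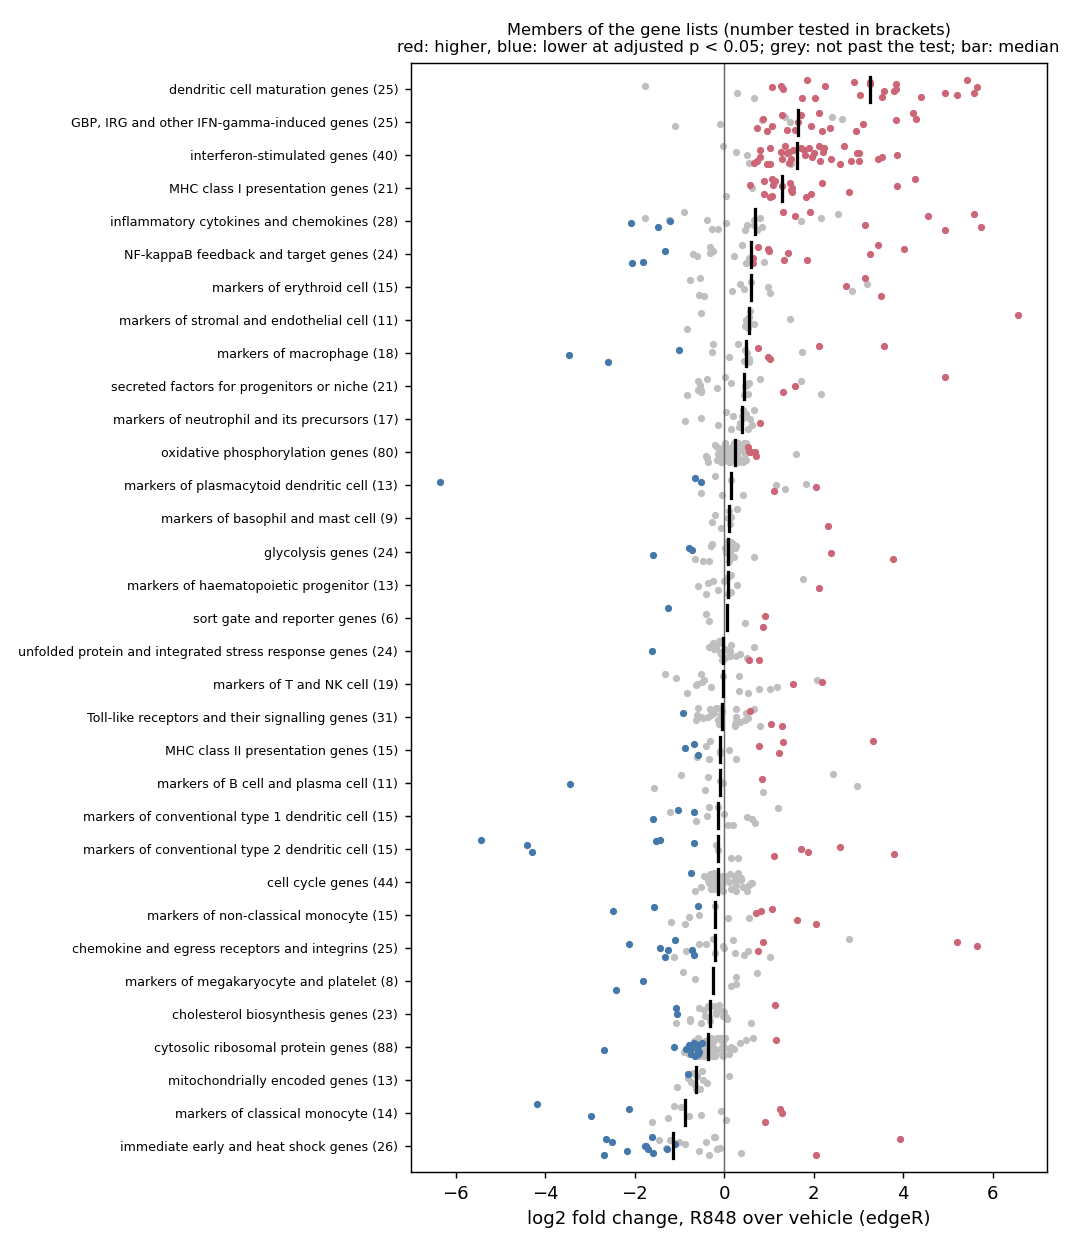
Log2 fold changes of R848 over vehicle for each tested member of the 33 gene lists, 1 point per gene, with members past the test in red when higher and blue when lower, and a black bar at the list's median. The maturation list has the highest median, 3.26, and the immediate early and heat shock list the lowest, -1.15.

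Inflammatory cytokine and chemokine genes rose in 8 and fell in 3 of 28 cases (10 and 3 adjusted over the list alone). The list had 5 rises without R848 replicate 1 or 3. As a set, these genes had a median log2 fold change of 0.70 (camera adjusted p = 0.00645; adjusted p = 0.365 with an estimated correlation). That median was 0.45 without R848 replicate 3. Cxcl16, which encodes the CXCR6 ligand, rose from 63.5 ± 11.5 to 565 ± 175 CPM (log2 fold change 3.15, SE 0.23, adjusted p = 7.64e-06). The chemokine gene Ccl9 fell from 405 ± 98.6 to 95.9 ± 13.8 CPM (log2 fold change -2.08, SE 0.20, adjusted p = 6.52e-05). The series also concerns haematopoietic progenitors, so secreted factors that act on progenitors or their niche formed a list of their own. In it, 3 of 21 tested genes rose and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.288). These were Il15 (6.94 ± 0.894 to 20.8 ± 3.76 CPM, log2 fold change 1.58, SE 0.22, adjusted p = 6.01e-04), Il6 (0.145 ± 0.167 to 4.58 ± 3.09 CPM, log2 fold change 4.92, SE 1.01, adjusted p = 0.00796) and Il1b (log2 fold change 1.31, adjusted p = 0.0345), the last outside the naming rule and named after its value was seen. The call on Il6 was lost without R848 replicate 3 and with limma-voom (adjusted p 2.24e-06 to 0.0934 over its alternatives), and this list had 1 rise without R848 replicate 3.

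Toll-like receptors and their signalling genes showed 3 rises and 1 fall among 31 tested (5 and 2 adjusted over the list alone; camera adjusted p = 0.657). The list showed 2 falls without vehicle replicate 1. Tlr1, which encodes a partner of TLR2, rose from 95.4 ± 28.2 to 234 ± 36.6 CPM (log2 fold change 1.30, SE 0.22, adjusted p = 0.00282). Tlr2 fell from 108 ± 23.3 to 56.5 ± 2.37 CPM (log2 fold change -0.93, SE 0.18, adjusted p = 0.00563). Neither Tlr7 nor Tlr8 passed the main test. Tlr7 was at 37 ± 13.5 and 58.5 ± 12.4 CPM in vehicle and R848 (adjusted p = 0.147) and Tlr8 at 34 ± 12.2 and 26.5 ± 4.22 CPM (adjusted p = 0.483). Tlr7 passed only without vehicle replicate 2 (adjusted p = 0.0376; range over alternatives 0.0376 to 0.494), and both genes lie on the X chromosome. Chemokine and egress receptors and integrins divided into 4 rises, with Ccr7 and Itgax among them, and 7 falls among 25 (7 and 10 adjusted over the list alone; camera adjusted p = 0.504). The list gave 2 rises without R848 replicate 1 or 3, 3 falls without R848 replicate 1 and 4 falls without R848 replicate 3. Ccr2, the receptor gene for monocyte recruitment, fell from 1452 ± 451 to 330.4 ± 119 CPM (log2 fold change -2.14, SE 0.29, adjusted p = 6.63e-04).

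Of the markers of conventional type 2 dendritic cells, 5 of 15 were higher and 6 lower (5 and 6 adjusted over the list alone). The test found 1 rise without R848 replicate 3 and 3 rises without vehicle replicate 4. The list's median log2 fold change was -0.14 (camera adjusted p = 0.0559). It was -0.21, -0.02 and -0.04 without vehicle replicates 1, 3 and 4, and -0.09 without R848 replicate 3. That list passed without vehicle replicate 1, 3 or 4 or R848 replicate 2 or 3 (adjusted p from 0.00465 to 0.0397; adjusted p = 0.344 with an estimated correlation). It also passed with DESeq2, the stricter filter (median -0.44), the replicate block (median -0.03), the GC and length offsets, and fry. The lectin gene Clec10a fell from 366 ± 107 to 18.7 ± 10.2 CPM (log2 fold change -4.29, SE 0.40, adjusted p = 1.16e-04). Sirpa, a signal-regulatory receptor gene and the most abundant member, was at 1042 ± 107 and 1159 ± 12.9 CPM (adjusted p = 0.563). Of 15 conventional type 1 markers, 3 were lower and none higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.278), and the list passed without vehicle replicate 1 (adjusted p = 0.0329; range over alternatives 0.0329 to 0.891). The list had 1 rise without vehicle replicate 3 or R848 replicate 2 and 1 fall without vehicle replicate 2 or R848 replicate 1 or 2. The lysosomal amidase gene Naaa fell from 352 ± 53.4 to 172 ± 23.4 CPM (log2 fold change -1.03, SE 0.16, adjusted p = 0.00167). Wdfy4, needed for cross-presentation, stood at 1445 ± 169 and 1103 ± 231 CPM (adjusted p = 0.186), and passed as lower with limma-voom alone (adjusted p = 0.0340; range over alternatives 0.0340 to 0.645). Plasmacytoid markers gave 2 rises and 3 falls among 13 (2 and 3 adjusted over the list alone; camera adjusted p = 0.560), with Cd209d among the falls. The test gave 1 rise without R848 replicate 3 and 1 fall without vehicle replicate 2 or 3 or any 1 R848 replicate. Tcf4, the plasmacytoid lineage factor gene, fell from 155 ± 20.7 to 109 ± 10.04 CPM (log2 fold change -0.52, SE 0.15, adjusted p = 0.0438), a call lost without vehicle replicate 2 or 3 or any 1 R848 replicate, without the low-count filter and with GC and length offsets (adjusted p 0.0107 to 0.206 over its alternatives).

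Classical monocyte markers fell in 3 and rose in 3 of 14 cases (8 and 3 adjusted over the list alone). The list showed 5 falls without vehicle replicate 1. The list's members had a median of -0.87 on the log2 scale (camera adjusted p = 7.56e-04; adjusted p = 0.344 with an estimated correlation). Fn1, on chromosome 1 from 71585520 to 71653200 in mm10, encodes fibronectin and fell from 955 ± 110.3 to 52.5 ± 13 CPM (log2 fold change -4.19, SE 0.21, adjusted p = 1.22e-06). The coagulation factor gene F13a1 and Ccr2 were the other falls. Non-classical monocyte markers gave 5 rises and 3 falls among 15 (6 and 6 adjusted over the list alone; camera adjusted p = 0.982). The list gave 2 rises without R848 replicate 1 or 3, 3 rises without vehicle replicate 2 and 1 fall without R848 replicate 1 or 3. The enolase gene Eno3 rose from 31.1 ± 12.5 to 95.9 ± 12 CPM (log2 fold change 1.62, SE 0.29, adjusted p = 0.00366). Spn, which encodes CD43, fell from 485 ± 70.3 to 321 ± 49.4 CPM (log2 fold change -0.60, SE 0.16, adjusted p = 0.0355), a call lost without vehicle replicate 2, 3 or 4 or R848 replicate 1 or 3 and with the replicate block (adjusted p 0.00306 to 0.226 over its alternatives). Macrophage markers rose in 5 and fell in 3 of 18 cases (8 and 3 adjusted over the list alone; camera adjusted p = 0.428). The test found 3 rises without vehicle replicate 4 or R848 replicate 1 or 3. The haemoglobin scavenger receptor gene Cd163 fell from 131 ± 45.1 to 11.9 ± 2.90 CPM (log2 fold change -3.46, SE 0.30, adjusted p = 2.42e-05). Csf1r, the receptor gene for macrophage colony-stimulating factor, fell from 871 ± 143 to 431 ± 26.8 CPM (log2 fold change -1.02, SE 0.16, adjusted p = 0.00138).

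**Figure D3:**
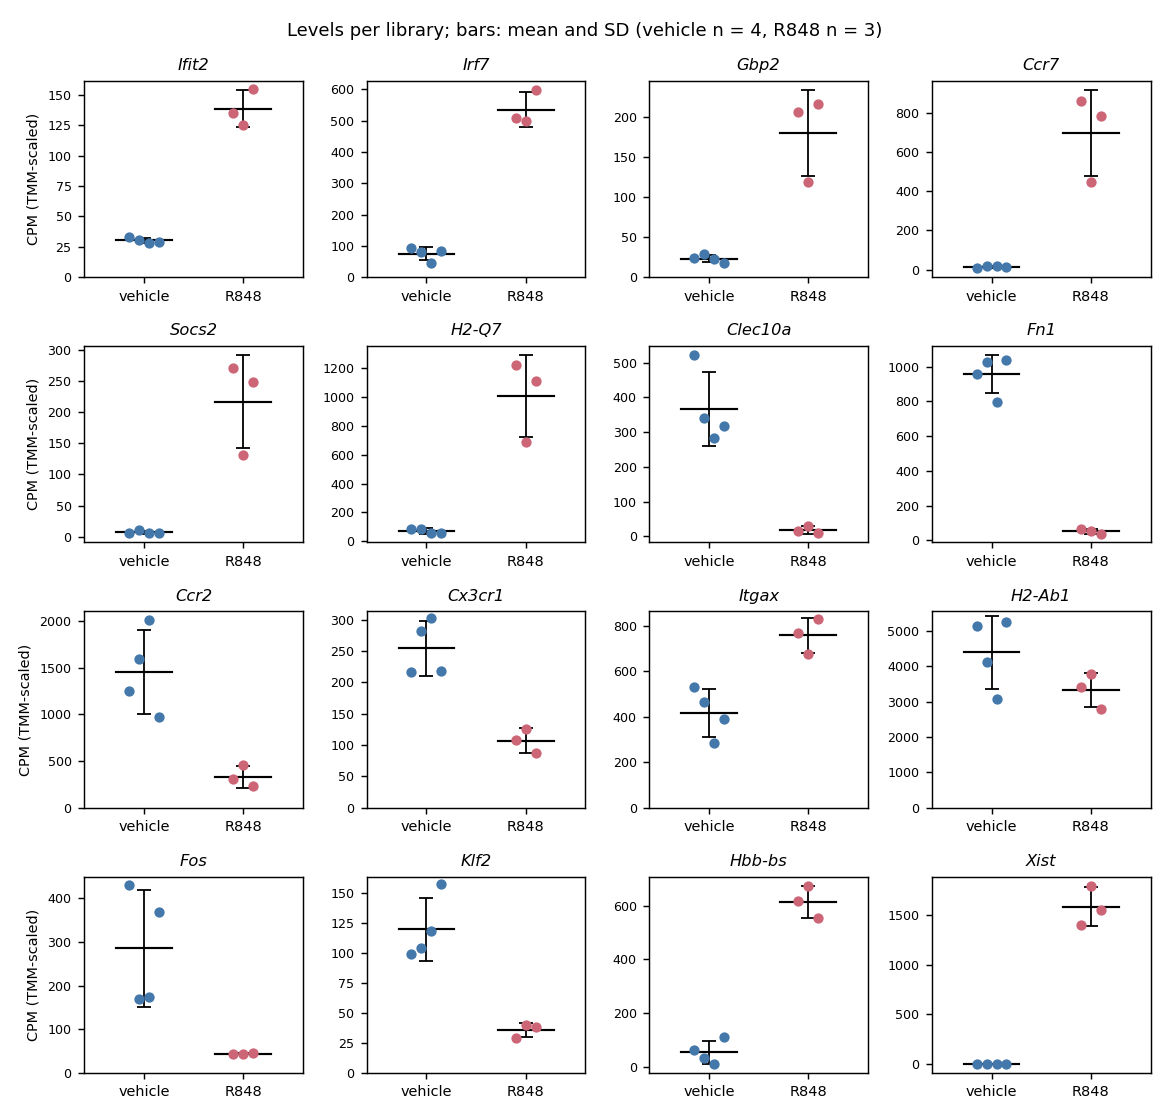
Level in each library, in TMM-scaled CPM, of 16 genes, with each point a library, horizontal bars the mean and error bars the SD (vehicle n = 4, R848 n = 3). Ccr7 rises from 14.1 ± 6.01 to 699 ± 221 CPM and Fn1 falls from 955 ± 110.3 to 52.5 ± 13 CPM, while Xist divides the same libraries.

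Among markers of other marrow cells, haemoglobin transcripts moved with the treatment. The 4 globin genes took 0.0144% ± 0.0138 of counts in vehicle and 0.136% ± 0.0124 in R848 libraries. Of 15 erythroid markers, 3 rose and none fell (4 and 0 adjusted over the list alone). The list had 1 rise without any 1 R848 replicate and 8 rises without vehicle replicate 4. As a set, these genes had a median log2 fold change of 0.59 (camera adjusted p = 0.00843; adjusted p = 0.826 with an estimated correlation). Hbb-bs, a beta-globin gene, rose from 54 ± 43 to 614 ± 60.7 CPM (log2 fold change 3.50, SE 0.70, adjusted p = 0.0191). Alas2, which encodes the erythroid enzyme that starts haem synthesis, rose from 4.53 ± 3.22 to 30.2 ± 1.84 CPM (log2 fold change 2.72, SE 0.50, adjusted p = 0.00591). The call on Hbb-bs was lost without any 1 of the R848 replicates and without the low-count filter (adjusted p 5.53e-05 to 0.0936 over its alternatives). With all libraries, Alas2 and Hbb-bs were among the 3 rises, so not every globin gene passed the test. Where an R848 replicate was left out, the list's 1 rise was Alas2, so no globin gene was called. The erythroid list's call was lost without vehicle replicate 1 (adjusted p = 0.109, range over alternatives 2.25e-14 to 0.826). It was also lost with DESeq2 (adjusted p = 0.0714) and with fry (adjusted p = 0.185). The list's median was 0.30, 0.39 and 2.00 without vehicle replicates 1, 2 and 4. Globin paralogs share reads, so their separate levels are uncertain. Neutrophil-lineage markers gave 1 rise among 17 and no fall (1 and 0 adjusted over the list alone; camera adjusted p = 0.148), called without vehicle replicate 4 (adjusted p = 0.0272; range over alternatives 0.0127 to 0.891) and with the replicate block. The test gave no rise without R848 replicate 1 or 3, 2 rises without vehicle replicate 2 and 1 fall without vehicle replicate 3. Lcn2, an iron-scavenging protein gene, rose from 35.6 ± 7.45 to 61.8 ± 7.97 CPM (log2 fold change 0.79, SE 0.19, adjusted p = 0.0168), a call lost without R848 replicate 1 or 3 (adjusted p 0.00175 to 0.0899 over its alternatives). The granule enzyme gene Mpo was at 346 ± 147 and 356 ± 84.3 CPM (adjusted p = 0.961).

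B-lineage markers gave 1 rise and 1 fall among 11 (3 and 1 adjusted over the list alone; camera adjusted p = 0.875). The list showed no rise without R848 replicate 3 and 2 rises without vehicle replicate 2 or R848 replicate 2. Fcer2a, which encodes CD23, fell from 7.45 ± 2.94 to 0.689 ± 0.279 CPM (log2 fold change -3.44, SE 0.46, adjusted p = 5.02e-04). Cd22 was at 96.1 ± 18 and 71.4 ± 9.53 CPM (adjusted p = 0.158). T and NK cell markers gave 2 rises among 19 and no fall (2 and 0 adjusted over the list alone; camera adjusted p = 0.278), and the list passed without vehicle replicate 3 (adjusted p = 0.00842; range over alternatives 0.00842 to 0.891) and with limma-voom. The list gave 1 rise without R848 replicate 1 and 4 rises without vehicle replicate 3. Cd8a, which some dendritic cells also express, rose from 4.97 ± 1.97 to 22.5 ± 7.06 CPM (log2 fold change 2.18, SE 0.34, adjusted p = 0.00156). Klrk1, which encodes NKG2D, was at 109 ± 43.9 and 187 ± 30.2 CPM (adjusted p = 0.0895) and passed without vehicle replicate 3 (adjusted p = 0.00704; range over alternatives 0.00472 to 0.317). DESeq2, limma-voom and the GC and length offsets also called Klrk1. Haematopoietic progenitor markers gave 1 rise among 13 and no fall (1 and 0 adjusted over the list alone; camera adjusted p = 0.416). The test found 2 rises without vehicle replicate 1. The transcription factor gene Sox4 rose from 13.4 ± 1.08 to 57.9 ± 12.4 CPM (log2 fold change 2.11, SE 0.18, adjusted p = 2.42e-05). The receptor gene Kit was at 146 ± 41.6 and 122 ± 17.3 CPM (adjusted p = 0.557). Basophil and mast cell markers gave 1 rise among 9 and no fall (1 and 0 adjusted over the list alone; camera adjusted p = 0.608). The list had no rise without R848 replicate 3. Cd200r3 rose from 1.64 ± 0.807 to 8.19 ± 3.65 CPM (log2 fold change 2.31, SE 0.50, adjusted p = 0.0102), a call lost without R848 replicate 3 and with the replicate block (adjusted p 1.31e-04 to 0.0786 over its alternatives). The basophil protease gene Prss34 was at 38.8 ± 23.8 and 33.9 ± 3.01 CPM (adjusted p = 0.865).

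Megakaryocyte and platelet markers gave 2 falls among 8 and no rise (2 and 0 adjusted over the list alone). The list's median log2 fold change was -0.26 (camera adjusted p = 0.0441; adjusted p = 0.380 with an estimated correlation). Itgb3, an integrin gene that myeloid cells also express, fell from 41.8 ± 7.51 to 11.8 ± 1.03 CPM (log2 fold change -1.82, SE 0.19, adjusted p = 9.99e-05). The list's call was lost without vehicle replicate 2 or 4 or R848 replicate 2 or 3 (adjusted p 0.00384 to 0.380 over its alternatives). Upper-quartile scaling, limma-voom, the replicate block and fry also gave no call (adjusted p = 0.0549, 0.0961, 0.242 and 0.0602). The list's median was -0.49 and 0.34 without vehicle replicates 3 and 4 and -0.51 without R848 replicate 1. Stromal and endothelial markers gave 1 rise among 11, that of Kdr, and no fall (1 and 0 adjusted over the list alone). The test gave 2 rises without vehicle replicate 1, 3 or 4. The list's members had a median of 0.55 on the log2 scale (camera adjusted p = 0.0404; adjusted p = 0.376 with an estimated correlation). That median was 0.36, 0.30 and 0.95 without vehicle replicates 1, 3 and 4, and 0.10 without R848 replicate 1. The list's call was lost without vehicle replicate 3 (adjusted p = 0.131, range over alternatives 3.13e-04 to 0.376). DESeq2, limma-voom and the fit without the low-count filter also gave no call for this list (adjusted p = 0.0702, 0.188 and 0.0541). Vcam1, an adhesion molecule gene, was at 115 ± 67.5 and 169 ± 15.6 CPM (adjusted p = 0.468).

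The list of immediate early and heat shock genes gave 11 falls, none of them in a heat shock gene, and 2 rises among 26 (13 and 2 adjusted over the list alone). The list showed 7 falls without R848 replicate 3. The set's median log2 fold change was -1.15 (camera adjusted p = 9.26e-06; adjusted p = 0.380 with an estimated correlation and 0.0888 with fry). Fos, an AP-1 subunit gene, fell from 285 ± 134 to 44.1 ± 1.74 CPM (log2 fold change -2.70, SE 0.34, adjusted p = 5.58e-04). Klf2, a quiescence-associated transcription factor gene, fell from 119.8 ± 26.3 to 35.8 ± 5.76 CPM (log2 fold change -1.74, SE 0.20, adjusted p = 1.76e-04). Both rises, Nr4a3 (log2 fold change 3.93, adjusted p = 6.15e-04) and Dusp2 (2.04, adjusted p = 0.00106), were named after their values were seen. Cytosolic ribosomal protein genes gave 16 falls and 1 rise among 88 (18 and 1 adjusted over the list alone). The list gave 2 rises without vehicle replicate 2, 1 fall without R848 replicate 1 or 3 and 8 falls without vehicle replicate 2. The list's median log2 fold change was -0.37 (camera adjusted p = 6.61e-07; adjusted p = 0.506 with an estimated correlation and 0.0702 with fry). Their share of counts was 2.42% ± 0.177 in vehicle and 1.81% ± 0.251 in R848 libraries. Rps27l, a p53-responsive member, rose from 33.2 ± 6.02 to 74.3 ± 11.9 CPM (log2 fold change 1.16, SE 0.18, adjusted p = 0.00134). Rps3a3, a copy of Rps3a1 whose reads are hard to separate, fell from 33.5 ± 18.2 to 5.24 ± 0.216 CPM (log2 fold change -2.68, SE 0.44, adjusted p = 0.00255).

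Mitochondrially encoded genes gave 1 fall among 13 and no rise (2 and 0 adjusted over the list alone). The test found no fall without vehicle replicate 2 or 3 or any 1 R848 replicate and 3 falls without vehicle replicate 1 or 4. The list's members had a median of -0.64 on the log2 scale (camera adjusted p = 0.0185; adjusted p = 0.869 with an estimated correlation). Without vehicle replicate 3 that median was -0.31. The respiratory complex I gene mt-Nd4 fell from 553 ± 184 to 315 ± 1.67 CPM (log2 fold change -0.81, SE 0.23, adjusted p = 0.0396), a call lost without vehicle replicate 2 or 3 or any 1 R848 replicate (adjusted p 0.00336 to 0.156 over its alternatives). The list's call was lost without vehicle replicate 2 (adjusted p = 0.0724) or 3 (adjusted p = 0.132; range over alternatives 5.05e-04 to 0.869). Fry also gave no call for this list (adjusted p = 0.394). Nuclear oxidative phosphorylation genes gave 5 rises among 80 and no fall (1 and 0 adjusted over the list alone). The list had 1 rise without R848 replicate 1 or 3, 2 rises without vehicle replicate 1 or 3 or R848 replicate 2 and 3 rises without vehicle replicate 2. The median of the list was 0.24 (camera adjusted p = 0.0196; adjusted p = 0.627 with an estimated correlation). The call was lost with GC and length offsets (adjusted p = 0.0553), and without vehicle replicate 1 (adjusted p = 0.0912) or R848 replicate 2 (adjusted p = 0.0794; range over alternatives 0.00129 to 0.627). Cox5a rose from 49 ± 5.16 to 78.5 ± 5.60 CPM (log2 fold change 0.68, SE 0.14, adjusted p = 0.00851). Uqcrq rose from 27.7 ± 4.91 to 45.1 ± 2.88 CPM (log2 fold change 0.70, SE 0.17, adjusted p = 0.0198), a call lost without R848 replicate 1 or 3 (adjusted p 0.00323 to 0.106 over its alternatives).

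Glycolysis genes gave 2 rises and 3 falls among 24 (2 and 3 adjusted over the list alone; camera adjusted p = 0.681). The test gave no fall without R848 replicate 3 and 1 fall without R848 replicate 1. Pfkfb3, which makes the activator of phosphofructokinase, rose from 172 ± 11.7 to 895 ± 225 CPM (log2 fold change 2.38, SE 0.18, adjusted p = 1.06e-05). The enolase gene Eno2 rose from 1.85 ± 1.57 to 24.8 ± 4.64 CPM (log2 fold change 3.77, SE 0.49, adjusted p = 5.44e-04). Cholesterol synthesis genes gave 1 rise and 2 falls among 23 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0954), and the list passed without vehicle replicate 1 or 4 or R848 replicate 1 (adjusted p from 0.0218 to 0.0358; over all alternatives 0.0218 to 0.891). Limma-voom and the replicate block also called the list. The list showed 2 rises without vehicle replicate 4, no fall without vehicle replicate 2 or R848 replicate 1 or 3 and 1 fall without vehicle replicate 3 or 4 or R848 replicate 2. Pmvk rose from 18.7 ± 2.79 to 41.3 ± 11.1 CPM (log2 fold change 1.14, SE 0.21, adjusted p = 0.00388). Unfolded protein and integrated stress response genes gave 2 rises and 1 fall among 24 (2 and 1 adjusted over the list alone; camera adjusted p = 0.952). The list gave no rise without R848 replicate 1, 1 rise without vehicle replicate 2 or R848 replicate 3 and no fall without vehicle replicate 1 or 4 or any 1 R848 replicate. The rises were in Herpud1 (126 ± 8.19 to 184 ± 16.4 CPM, log2 fold change 0.55, SE 0.13, adjusted p = 0.0169) and Sesn2 (25.3 ± 5.40 to 43.2 ± 4.93 CPM, log2 fold change 0.77, SE 0.19, adjusted p = 0.0224). Both calls were lost without R848 replicate 1, that on Herpud1 also with the replicate block and that on Sesn2 without R848 replicate 3 or vehicle replicate 2 (adjusted p 0.00108 to 0.130 and 0.00336 to 0.127 over their alternatives).

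Cell cycle genes gave a single fall among 44 and no rise (0 and 0 adjusted over the list alone). The test found 3 rises without vehicle replicate 4, no fall without vehicle replicate 1, 3 or 4 or R848 replicate 1 or 3 and 5 falls without R848 replicate 2. The median of the list was -0.15 (camera adjusted p = 0.483). It was 0.01 without vehicle replicate 4 and -0.01, -0.28 and -0.01 without R848 replicates 1, 2 and 3, and the list passed without R848 replicate 2 (adjusted p = 0.00312; range over alternatives 0.00312 to 0.967). Kif23, a cytokinesis motor gene, fell from 168 ± 25 to 101 ± 34.7 CPM (log2 fold change -0.74, SE 0.22, adjusted p = 0.0490), with overlapping libraries. Its call was lost without vehicle replicate 1, 3 or 4 or R848 replicate 1 or 3, with total counts only and with the replicate block (adjusted p 0.00460 to 0.262 over its alternatives).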

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

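Among the 4 vehicle libraries, 93 values (the log2 CPM of the named genes and 7 library measures) were checked for a library far from the others by the gap to its nearest neighbour as a share of the group's range. Chance gives about 1 in 20, here 4.65, and 7 passed Dixon's 95% bound for 4 samples. A gene with counts in a single vehicle library has a gap share of 1 whatever its level. Xist, Grpr and Ly6c1 passed in this way, so the 7 are no evidence of an excess over chance. Irf7 was low in vehicle replicate 3 (44.9 CPM against 81.9 to 92.0 in the others; gap share 0.838). Cacnb3 was low in vehicle replicate 4 (10.1 CPM against 14.2 to 14.8; 0.891), and Socs2 was high in vehicle replicate 2 (10.4 CPM against 5.90 to 6.19; 0.916). Xist was seen in vehicle replicate 3 alone (1.45 CPM; gap share 1), and Grpr and Ly6c1 in vehicle replicate 4 alone (0.108 and 0.0811 CPM; gap share 1 for each), from 36, 4 and 3 counts over the vehicle group. The share of values that were not whole was high in vehicle replicate 4 (42.0% against 33.3% to 34.6%; 0.842). All R848 levels of Irf7, Cacnb3 and Socs2 lay above every vehicle library.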

How the results depend on the processing

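Of the 16 or 17 alternatives that could be applied to each of the tested named genes, none turned a direction among genes called in either setting. Calls were the same throughout for 61 of 84 tested genes, and 18 of the 71 named genes past the test lost their call in at least 1 alternative. The median of the megakaryocyte and platelet list, called at -0.26, was 0.54 with the replicate block and 0.34 without vehicle replicate 4, where the call was lost. That of the T and NK cell list, not called at -0.04, was 0.57 without vehicle replicate 3 and 0.59 with limma-voom, where it was called. The number of genes changed was 2064 (1212 higher, 852 lower). It was 1110 (720 and 390) at an adjusted p under 0.01, 1269 (829 and 440) at a fold of at least 2, and 938 (646 and 292) with glmTreat against 1.5-fold, which are stricter by construction. Limma-voom gave 1312 genes lower. Leaving out single libraries gave 1060 to 2210 changed, 705 to 1303 higher and 355 to 907 lower, lowest without R848 replicate 1 (1060, of which 1058 were shared with the full set) and replicate 3 (1100, of which 1091 were shared), where 2 libraries remain. The camera list count of 14 was 0 with estimated correlations (4 at an unadjusted p under 0.05; fry gave 10) and 28 with fry's mixed test, which asks another question. Of the gate genes, 3 were called, 1 to 4 without single libraries (1 without R848 replicate 1) and 5 with GC and length offsets, an alternative chosen after seeing the data; the cause was not tested. With autosomal genes alone, also chosen then, 2019 genes were called. Same-numbered libraries did not deviate together (r = 0.04, -0.03 and 0.04 across genes), and R848 replicates 1 and 3 but not 2 correlated best with their own number. The replicate block gave 1708 changed genes (1055 higher, 653 lower), 16 lists and 3 gate genes. Depth limits the lowest genes: Ly6g and Ly6c1 could not be tested.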

Other observations

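Tests of the sex and library series, of the erythroid markers and of the type 2 dendritic cell markers were chosen after the results were seen, as were the genes of the next paragraph and the offsets for GC content and length.

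Further genes of the lists were examined. Il12b, which encodes a subunit of IL-12 and IL-23, rose from 0.697 ± 0.614 to 36.8 ± 12.3 CPM (log2 fold change 5.74, SE 0.80, adjusted p = 0.00217). Fscn1, the gene of an actin-bundling protein of mature dendritic cells, rose from 31.3 ± 14.9 to 1157 ± 402 CPM (log2 fold change 5.21, SE 0.48, adjusted p = 1.97e-04). Cxcr5, a follicle-homing receptor gene, rose from 0.488 ± 0.519 to 17 ± 12.6 CPM (log2 fold change 5.20, SE 0.98, adjusted p = 0.00934). The amino acid oxidase gene Il4i1 rose from 27.5 ± 14.8 to 394 ± 123 CPM (log2 fold change 3.84, SE 0.38, adjusted p = 1.89e-04). Gadd45b rose from 11.6 ± 5.77 to 187 ± 65.5 CPM (log2 fold change 4.01, SE 0.50, adjusted p = 0.00108). The co-stimulatory gene Cd86 did not pass the test, at 38.6 ± 9.99 and 47.4 ± 5.69 CPM (adjusted p = 0.477). Cd40, another such gene, rose from 19.1 ± 3.19 to 64 ± 17.6 CPM (log2 fold change 1.74, SE 0.21, adjusted p = 2.57e-04). Among the R848 libraries, the mean log2 CPM of the maturation list was 7.33, 6.56 and 7.17 in replicates 1, 2 and 3, against 3.84 to 4.45 in the vehicle libraries.

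Interferon-stimulated, maturation and MHC class I genes were higher in R848. Trends with GC content and length argue little for it: with offsets for them, 75 of the 76 members called higher were still called, and the medians of the lists were 1.66, 3.16 and 1.22. Of the 35 splits of the libraries into 4 and 3, only the real one called as many genes as the 2064 found. Its share, 1 of 35 or 2.86%, is the smallest that these splits can give. The others called 0 with edgeR, with at most 3128 genes at an unadjusted p under 0.05 against 4151. Splits that mix the groups also widen the spread within a side, which favours few calls. A chance split is thus an unlikely source of that count, but it is not excluded, since the libraries may not be separate animals. The number of lists is different, since 8 of the 35 splits called 14 or more with camera at the preset correlation and the highest other gave 19, so chance cannot be excluded for it. The sex of the animals and the library series cannot be told apart from the treatment, because 0 libraries share a sex type or column series with the other group, and this holds for every pattern here.

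Haemoglobin transcripts were higher in R848 although the gate selects MHC class II-high cells. With all libraries not every globin gene passed the test, and without any 1 R848 replicate none did. Nucleated erythroid cells would bring their other transcripts too. The 10 other erythroid markers had a median log2 fold change of 0.26 (SD 0.66), below the lowest globin value of 2.85. This difference does not decide against such cells, because a marker already present in vehicle would rise less from a few of them. Without vehicle replicate 4, where these markers were highest, the values were 1.39 and 4.08, still apart by more than the SD. In that fit 8 members of the list were called higher, so some of the 10 other markers rose with the globins and Alas2. RNA of late red cells carried into the sort is another candidate. Alas2 (2.72, SE 0.50) moved like the globins, which are the most abundant of the list (Hbb-bs 614 ± 60.7 CPM in R848). Alas2 is an erythroid marker as well, so its rise does not tell such RNA from nucleated erythroid cells. It also lies on the X chromosome, and sex type could not be separated from treatment. Of the list's genes, 7 had a vehicle mean of at least 10 CPM.

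Cd209a, Clec10a, Mgl2, Fn1, F13a1 and Ccr2 were lower in R848, with log2 fold changes of -4.40, -4.29, -5.43, -4.19, -2.98 and -2.14, and the first 3, the lowest members of the type 2 list, were picked after their values were seen. Fn1, F13a1 and Ccr2 were the 3 falls of the classical monocyte list, which also had 3 rises, and the type 2 check does not cover them. Fewer type 2 conventional dendritic cells in the gate would lower alike the markers that only they express. The 12 others of the type 2 list went both ways (5 higher and 3 lower). The rises numbered 1 without R848 replicate 3 and 3 without vehicle replicate 4. The median of all 15, the first 3 included, was -0.14. The median of the 12, 0.23 (SD 1.63), lay above -4.29, the highest value of the first 3. In all 7 fits that left out a library, it stayed above that fit's own highest value by more than its SD. The first 3 were picked as the lowest members, which favours such a gap. The list's members thus did not all fall together. Even so, fry called the list lower (adjusted p = 0.00150), as did camera in several alternatives. The mixed directions do not decide against fewer such cells, because markers that other cells of the gate share need not fall. GC content and length argue little for the falls, since all 6 genes were still called lower with offsets. As a hypothesis, a subset that expresses these genes may have been lost from the gate, or the genes may have been turned down within cells during maturation. Bulk libraries with this confounding leave both open: counts of the subset and levels per cell would tell them apart, and neither was analysed here.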
